A study of Mus musculus with 4 samples.

How the data were processed

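RNA of sorted BCR-ABL-expressing mouse leukemia stem cells was measured on 4 Affymetrix whole-transcript arrays, 2 of WT and 2 of Hif1a-/- donor origin, from mice of 8 weeks of age per the labels. The authors deposited 1 table of log2 expression values, 1 column per array and 35556 probe sets. Per the submitters' processing notes, the values came from Affymetrix Expression Console 1.1 with RMA, which corrects background, normalizes the arrays by quantiles and summarises the probes of a set; its further settings are not given in the sources used here. The columns ran from about 3.07 to 14.71, in the range of RMA values, and 0 columns were left unused. RMA draws small differences at low expression together, so differences of dim genes are understated, and it scales out any change of total RNA per cell.

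Samples were grouped by the genotype in their titles. Probe sets were named through the platform annotation given for the table: 21789 carried 1 gene symbol, 1621 several, and 12146 were unnamed here. Probe sets with 1 symbol were kept and each gene was represented by the set with the highest mean over the arrays, which left 19938 genes, 999 of them with more than 1 probe set. Symbols were looked up by Entrez number in the RefSeq gene table of assembly GRCm38.p6, which held 19856 of the genes and changed 0 symbols. Where probe sets of a named gene differed in sign or by much, the other value is given in the text.

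Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with genotype as the only term, on all 4 arrays, followed by Benjamini-Hochberg adjustment at a threshold of 0.05. The fit had 2 residual and 4.46 prior degrees of freedom. An exact permutation test of 2 against 2 arrays cannot give a two-sided p under 0.333, so single genes rest on limma's pooled variance. The 95% interval of Hif1a used the same moderated variance.

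Before the data were examined, 20 gene lists were fixed with 519 entries, of which 476 were measured; the other 43 had no probe set with a single symbol and were not analysed here. They covered HIF pathway components, glycolysis, hypoxia response, oxidative phosphorylation, DNA replication, mitosis, CDK inhibitors, p53 targets, apoptosis regulators, stem cell genes, granulocyte and monocyte, erythroid and megakaryocyte, lymphoid, mast cell and basophil, and stromal and endothelial genes, antioxidant genes, interferon response, kinase signalling targets, immediate early genes, and sex-linked genes, the last given as values only. The other 19 were tested with camera, which compares a list's moderated statistics with those of all other genes, two-sided, at a preset correlation of 0.01 between genes. Camera with an estimated correlation, camera on ranks and fry were alternatives. Fry's test asks whether a list's genes move on balance in 1 direction, without reference to other genes.

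The genes named in the text followed a rule fixed at the same time. It took Hif1a, up to 10 genes in each direction with the largest change among those past the threshold with groups that did not overlap, filled up by the smallest unadjusted p among genes with a log2 difference of at least 1, 3 genes with the smallest p from each list, and every CDK inhibitor and sex-linked gene. It left out predicted and unnamed transcripts, olfactory and vomeronasal receptors and small RNAs. It named 73 genes. Genes outside the rule are said to be named after their values were seen.

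The procedure was tested on simulated data drawn for 19938 genes, with variances drawn from limma's fitted prior distribution. In 20 data sets with 200 changed genes each, limma called 60.0% of 2-fold and 97.7% of 4-fold changes, with 8.6 false calls on average. In 100 data sets without any effect, camera at the preset correlation called 0.03 of 19 lists on average when genes varied independently, and a median of 6 when arrays varied along the difference between the WT arrays; the estimated correlation then gave a median of 0. A planted shift of the glycolysis list was called in 100% of data sets.

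The alternatives were filters at the 25th percentile and the median of mean expression, a second quantile normalization, centred array medians, a floor at the 25th percentile, a variance trend with and without robust fitting, the mean of all probe sets of a gene, all probe sets of the table, the replicate number as a block, each array left out in turn, and other thresholds. Array weights and 5 further lists (conventional dendritic cell, MHC class II, plasmacytoid dendritic cell, mature neutrophil and early granule genes) were added after the data had been seen.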

Results

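Gene expression was measured in leukemia stem cells from a mouse model of chronic myeloid leukemia. In this model, donor marrow is infected with a retrovirus for BCR-ABL, the fusion kinase that drives the disease, and for green fluorescent protein, and is then given to recipient mice. The cells were sorted from recipient marrow 14 days after transplantation, as fluorescent cells that lacked lineage markers and carried c-Kit and Sca-1. There were 2 samples from WT donor marrow and 2 from Hif1a-/- donor marrow, each on 1 Affymetrix whole-transcript array. The labels call them biological replicates and do not say that they came from separate animals, so the limma p-values measure only the spread between these samples. Camera's p at the preset correlation rests on the spread between genes. The samples enter it only through each gene's statistic, so a small value is no measure of agreement between samples. The deposited values were RMA log2 expression, with medians over the genes tested of 8.54 and 8.53 on WT replicates 1 and 2 and of 8.55 and 8.57 on Hif1a-/- replicates 1 and 2. The number of arrays limits the precision, and the median standard error of a difference between genotypes was 0.14 on the log2 scale over 19938 genes.

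The design poses 1 comparison, Hif1a-/- against WT, and asks which genes differ in BCR-ABL leukemia stem cells without Hif1a, the gene of the oxygen-regulated subunit of the transcription factor HIF-1. Hif1a itself read 11.42 ± 0.11 (SD, n = 2) in WT and 11.32 ± 0.10 (SD, n = 2) in Hif1a-/- cells. The difference was -0.09 on the log2 scale, with a 95% interval from -0.42 to 0.23 and an unadjusted limma p of 0.502, and it was -0.014 without WT replicate 2. The labels do not say which exons are deleted, and a probe set spread over a whole transcript can keep its signal when part of the gene is lost, so this value checks the genotype labels only weakly. Among the other HIF pathway genes, the difference was -0.13 for Epas1, which encodes the HIF-2 subunit, 0.04 for Arnt, the common partner subunit, -0.14 for Vhl and -0.45 for Egln3, an oxygen-sensing hydroxylase that differed by -0.019 without WT replicate 2. Hif3a differed by 0.37 (0.16 without Hif1a-/- replicate 1) and Arnt2 by -0.25, with groups that did not overlap and unadjusted limma p of 0.0945 and 0.113. Epas1, Arnt and Vhl were named after their values were seen. The differences were -0.010 for Epas1 and -0.15 for Arnt2 without Hif1a-/- replicate 1, and -0.082 for Arnt and -0.040 for Vhl without WT replicate 1. The list of 13 HIF pathway genes had a mean difference of -0.08, against 0.16 between WT replicate 2 and WT replicate 1, and was called lower by camera at an adjusted p of 0.0205. Its adjusted p = 0.564 with an estimated correlation, and the preset call ended without WT replicate 2 (mean -0.00087, adjusted p 0.605) or without Hif1a-/- replicate 2 (mean -0.05, adjusted p 0.225).

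Most glycolysis genes and part of the genes of the hypoxia response read lower in Hif1a-/- than in WT leukemia stem cells. Bnip3, a mitochondrial protein that marks mitochondria for removal, read 10.79 ± 0.04 (SD, n = 2) in WT and 9.50 ± 0.01 (SD, n = 2) in Hif1a-/- cells, a 2.44-fold difference. Plod2 and P4ha1, hydroxylases of collagen, were 1.91-fold and 1.72-fold lower in Hif1a-/- cells. Slc16a3, an exporter of lactate, was 1.83-fold lower, and Slc2a1, a glucose transporter, was 1.41-fold lower. Aldoc, an aldolase of glycolysis, was 1.36-fold lower.

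Of 21 measured glycolysis genes, 18 had a lower mean in Hif1a-/- cells and 3 a higher one. In 15 of them both Hif1a-/- arrays lay below both WT arrays, and in 0 both lay above, where chance gives 16.7% in each direction, 33.3% in all, and 9.05% of all genes measured lay below and 15.7% above. The list had a mean difference of -0.23 (SE 0.06 over its genes), and camera called it lower at an adjusted p of 1.91e-12. That adjusted p = 0.142 with an estimated correlation, and fry gave an adjusted p of 0.140. By limma, 6 glycolysis genes had an unadjusted p under 0.05, all lower, while 0 passed when adjusted over all genes and 0 when adjusted over the list alone, where the smallest adjusted p was 0.0942. The difference was -0.87 ± 0.23 (SE) for Slc16a3, with an unadjusted limma p of 0.00838, and -0.50 ± 0.14 (SE) for Slc2a1, with 0.00897. Other members differed less or the other way: Ldha, the lactate dehydrogenase subunit, by -0.09, Pdk1 by 0.11 and the lactate carrier Slc16a1 by 0.28. These 3 genes were named after their values were seen. Ldha differed by -0.061 without Hif1a-/- replicate 2, and the other pair turned without WT replicate 1 (-0.31 for Pdk1 and -0.077 for Slc16a1).

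Among 28 measured genes of the hypoxia response outside glycolysis, 20 had a lower and 8 a higher mean in Hif1a-/- cells. In 10 both Hif1a-/- arrays lay below both WT arrays and in 3 above, beside 16.7% in each direction by chance. The mean difference was -0.24 (SE 0.07 over the genes) and camera called the list lower, with an adjusted p of 1.03e-10. It had an adjusted p = 0.142 with an estimated correlation, and fry gave an adjusted p of 0.140. By limma, 0 of the 28 passed when adjusted over all genes, 3 passed when adjusted over the list alone (Bnip3, Plod2 and P4ha1), and 6 had an unadjusted p under 0.05, 5 lower and 1 higher. The differences were -1.29 ± 0.12 (SE) for Bnip3, with an unadjusted limma p of 2.40e-05 and an adjusted p of 0.239 over all genes, -0.94 ± 0.15 (SE) for Plod2 and -0.78 ± 0.14 (SE) for P4ha1. Vegfa, an angiogenic factor, differed by -0.11 and Car9, a carbonic anhydrase, by -0.30, with unadjusted limma p of 0.533 and 0.370, and both turned without WT replicate 2 (0.088 for Vegfa and 0.20 for Car9). The gene of the transferrin receptor, Tfrc, read 0.36 higher in Hif1a-/- cells, and these last 3 genes were named after their values were seen. A second probe set for Bnip3 differed by -0.95.

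**Figure D1:**
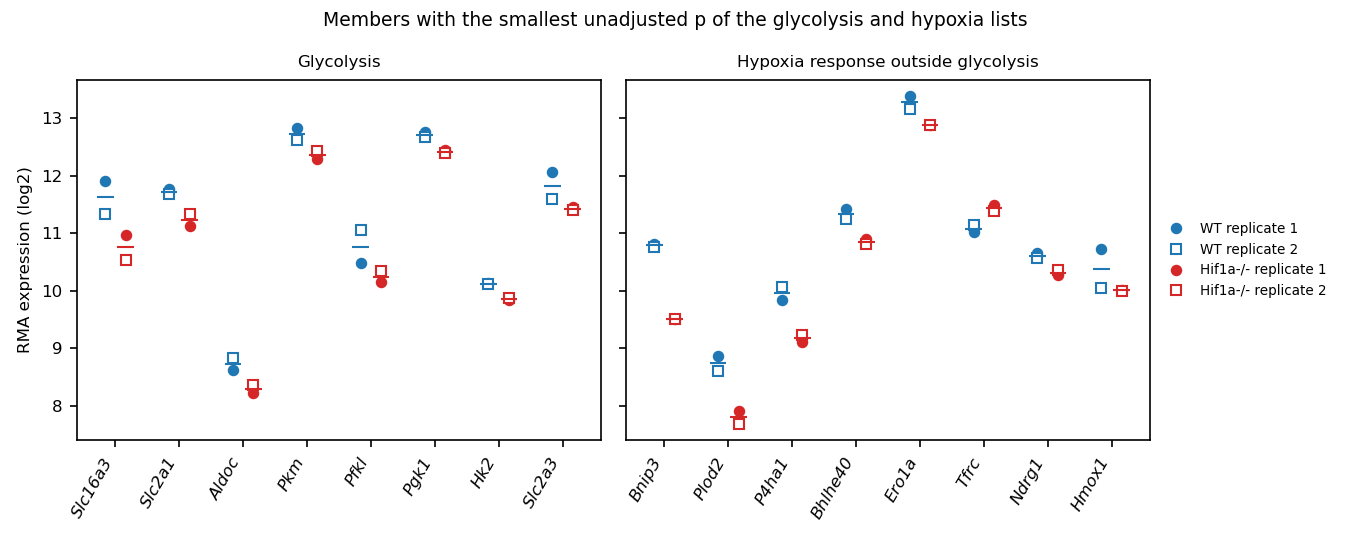
RMA log2 expression on each of the 4 arrays for the 8 glycolysis genes and the 8 hypoxia genes with the smallest unadjusted p, WT in blue and Hif1a-/- in red, with short lines at the group means. Bnip3 lies near 10.79 on both WT arrays and near 9.50 on both Hif1a-/- arrays, while Tfrc lies 0.36 higher in Hif1a-/- cells.

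Most genes of the erythroid and megakaryocyte list had a higher mean in Hif1a-/- cells. Sptb, which encodes a spectrin of the red cell skeleton, was 1.62-fold higher, Epor, the erythropoietin receptor, 1.60-fold, and Tspan33, a tetraspanin of erythroid progenitors, 1.53-fold. Sptb read 9.13 ± 0.02 (SD, n = 2) in WT and 9.82 ± 0.34 (SD, n = 2) in Hif1a-/- cells. Of 22 measured erythroid and megakaryocyte genes, 18 had a higher and 4 a lower mean, and in 12 both Hif1a-/- arrays lay above both WT arrays, beside 16.7% by chance in that direction and 15.7% of all genes. The mean difference was 0.32 (SE 0.07 over the genes), and camera called the list higher at an adjusted p of 1.08e-08. It had an adjusted p = 0.142 with an estimated correlation, and fry gave an adjusted p of 0.0195. By limma, 9 of these genes had an unadjusted p under 0.05, all higher, and 0 passed when adjusted over all genes or, with a smallest adjusted p of 0.0840, when adjusted over the list alone. Gata1, the erythroid transcription factor, differed by 0.12 and the megakaryocyte genes Itga2b and Vwf by -0.05 and 0.13. Further megakaryocyte genes of the list went both ways: Pf4 by 0.43, Gp5 by 0.37, Gp9 by 0.25, Treml1 by 0.18, Ppbp by -0.06 and Rab27b by -0.33. Klf1, the globin gene activator, differed by 0.29 and Rhag, a red cell membrane protein, by 0.84. Gata1, Klf1, Rhag and the megakaryocyte genes above were named after their values were seen. Without Hif1a-/- replicate 1 the differences were 0.46 for Sptb, 0.41 for Epor and 0.43 for Rhag, and -0.010 for Gata1 and 0.12 for Itga2b, while Vwf gave 0.071 without Hif1a-/- replicate 2.

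The mean of mast cell and basophil genes was lower in Hif1a-/- cells, with large differences in a few of them. Mcpt4, a chymase of connective tissue mast cells, read 9.54 ± 0.03 (SD, n = 2) in WT and 8.24 ± 0.03 (SD, n = 2) in Hif1a-/- cells, a 2.47-fold difference. The mast cell tryptase Tpsb2 was 1.83-fold lower and the chymase Cma1 1.81-fold lower, the latter with groups that overlapped, as did those of the tryptase Tpsab1, named after its values were seen (-0.62), and outside the list the proteases Mcpt1 and Mcpt2 were 2.97-fold and 3.10-fold lower. The sizes rest in part on Hif1a-/- replicate 1, without which the differences were -0.45 for Tpsb2, -0.35 for Cma1, -0.90 for Mcpt1 and -0.48 for Mcpt2. The basophil proteases Mcpt8 and Prss34, named after their values were seen, differed by -0.09 and -0.02, and by -0.0036 and 0.27 without WT replicate 1. All 13 measured mast cell and basophil genes had a lower mean in Hif1a-/- cells, and in 4 both Hif1a-/- arrays lay below both WT arrays, beside 16.7% by chance in that direction. The mean difference was -0.46 (SE 0.12 over the genes), and camera called the list lower at an adjusted p of 1.01e-10. That adjusted p = 0.301 with an estimated correlation, and fry gave an adjusted p of 0.448. By limma, 0 of the 13 passed when adjusted over all genes, 1 passed when adjusted over the list alone (Mcpt4, with an unadjusted p of 2.27e-05 and an adjusted p of 0.239 over all genes) and 2 had an unadjusted p under 0.05. The list lay at -0.44 on Hif1a-/- replicate 1 and at -0.01 on Hif1a-/- replicate 2, relative to each gene's mean over the arrays, and without Hif1a-/- replicate 1 the mean difference was -0.24 (adjusted p 6.80e-06).

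**Figure D2:**
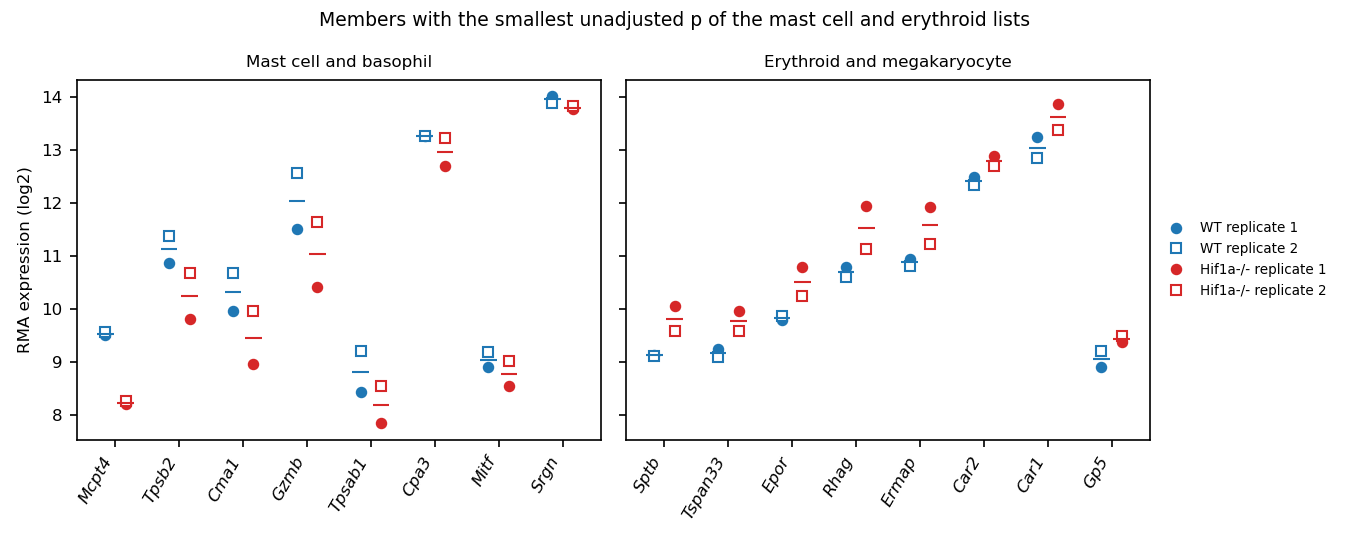
RMA log2 expression on each of the 4 arrays for the 8 mast cell and basophil genes and the 8 erythroid and megakaryocyte genes with the smallest unadjusted p, WT in blue and Hif1a-/- in red, with short lines at the group means. Mcpt4 lies near 9.54 on both WT arrays and near 8.24 on both Hif1a-/- arrays, while Gzmb overlaps between the groups.

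The means of the oxidative phosphorylation and DNA replication lists were slightly higher in Hif1a-/- cells, by less than the difference between the WT arrays. Of 41 oxidative phosphorylation genes, 35 had a higher mean, with differences of 0.24 for Atp5o, 0.21 for Uqcrh and 0.24 for Ndufb9. Of 34 DNA replication and G1/S genes, 31 had a higher mean, with 0.22 for Cdc6, 0.27 for Orc6 and 0.21 for Rfc4. Without WT replicate 1 the differences were 0.10 for Ndufb9, 0.11 for Orc6 and -0.012 for Rfc4, and without Hif1a-/- replicate 1 they were 0.15 for Atp5o and 0.10 for Cdc6. The mean difference was 0.10 for both lists, less than the 0.17 and 0.26 between WT replicate 2 and WT replicate 1, and camera called both higher, at adjusted p of 0.00523 for oxidative phosphorylation and 0.0373 for DNA replication. These gave adjusted p = 0.708 with an estimated correlation for oxidative phosphorylation and adjusted p = 0.718 with an estimated correlation for DNA replication. In both lists 0 genes had an unadjusted limma p under 0.05, and 0 passed when adjusted over the list alone or over all genes. Without WT replicate 1 the mean of oxidative phosphorylation was 0.01, with the camera direction turned (adjusted p 0.852), and that of DNA replication was -0.03 (adjusted p 0.307). Without Hif1a-/- replicate 1 the means were 0.07 (adjusted p 0.162) and -0.03 (adjusted p 0.136). Of 31 mitosis genes, 21 had a higher mean, among them Birc5 (0.14), Cdk1 (0.13) and Cenpa (0.12), or 0.082 for Birc5, 0.033 for Cdk1 and 0.067 for Cenpa without WT replicate 1, and the list was not called (mean 0.04, camera adjusted p 0.542). The mitosis list had a mean of -0.09 without WT replicate 1 (adjusted p 0.0134) and of 0.17 without WT replicate 2 (adjusted p 0.00165).

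The means of the immediate early and kinase signalling lists were slightly lower in Hif1a-/- cells, by less than the difference between the WT arrays. Of 21 immediate early and stress genes, 18 had a lower mean, with differences of -0.40 for Egr2, -0.37 for Nr4a1 and -0.24 for Fos. Without Hif1a-/- replicate 1 these were -0.24 for Egr2, -0.16 for Nr4a1 and -0.13 for Fos. The list mean was -0.15 (SE 0.03 over the genes), and camera called it lower at an adjusted p of 5.52e-06. It had an adjusted p = 0.318 with an estimated correlation. Between WT replicate 2 and WT replicate 1 its mean was -0.20, and without WT replicate 1 the mean was -0.05 (adjusted p 0.276). Of 29 kinase signalling targets, 18 had a lower mean, with -0.55 for Pim2, a survival kinase, -0.53 for Socs2 and -0.29 for Cish, both feedback inhibitors of cytokine signalling that STAT5 induces. A second probe set for Socs2 differed by -0.34, and the first by -0.16 without WT replicate 2, while without WT replicate 1 the differences were -0.35 for Pim2 and -0.14 for Cish. Their list mean was -0.09, called lower by camera at an adjusted p of 0.00554. It had an adjusted p = 0.301 with an estimated correlation. Between WT replicate 2 and WT replicate 1 its mean was -0.10, and without WT replicate 1 the mean was -0.04 (adjusted p 0.351). In each of these lists 1 gene had an unadjusted limma p under 0.05 (Egr2 and Pim2), and 0 passed when adjusted over all genes or over the list alone.

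The stem cell, granulocyte and interferon lists differed more between the WT arrays than between genotypes, as did 8 of the 12 called lists in all, every one but glycolysis, hypoxia response, erythroid and mast cell genes. The mean difference between genotypes was -0.06 for 37 stem cell genes, -0.06 for 34 granulocyte and monocyte genes and -0.11 for 23 interferon response genes. Between the WT arrays, replicate 2 minus replicate 1, the means were 0.45 (SE 0.09), -0.73 (SE 0.19) and -0.90 (SE 0.13). Camera called the 3 lists lower in Hif1a-/- cells at adjusted p of 0.0459, 0.0402 and 0.000927. These became adjusted p = 0.708 with an estimated correlation for stem cell genes, adjusted p = 0.662 with an estimated correlation for granulocyte genes and adjusted p = 0.708 with an estimated correlation for interferon genes. Without WT replicate 1 the granulocyte list was higher in Hif1a-/- cells (mean 0.30, adjusted p 5.40e-07) and so was the interferon list (mean 0.34, adjusted p 4.03e-07), and without WT replicate 2 the stem cell list was higher (mean 0.17, adjusted p 0.0101). The calls also ended without Hif1a-/- replicate 1 for stem cell genes (mean -0.0046, adjusted p 0.412) and granulocyte genes (mean -0.06, adjusted p 0.147), and without Hif1a-/- replicate 2 for interferon genes (mean -0.04, adjusted p 0.0559).

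Within these 3 lists, single genes went both ways. Erg, a transcription factor of stem cell maintenance, was 1.42-fold lower in Hif1a-/- cells, and Irf8, the regulator of monocyte and dendritic cell fate, was 1.51-fold lower, with unadjusted limma p of 0.0174 and 0.00460. Cebpa, the granulocyte regulator, differed by -0.31 and Ly86 by -0.61, and Mycn and Txnip by -0.45 and -0.24, and of these 4 genes only Cebpa had groups that did not overlap. Without WT replicate 2 the differences were -0.32 for Erg, -0.22 for Ly86 and -0.0029 for Mycn, and Cebpa gave -0.19 without Hif1a-/- replicate 1 and Txnip -0.091 without Hif1a-/- replicate 2. Both Hif1a-/- arrays lay above both WT arrays for the stem cell genes Tek (0.18), Fgd5 (0.12) and Mllt3 (0.22) and for the granulocyte list's Csf2ra (0.18), which were named after their values were seen. The differences were 0.034 for Tek and 0.078 for Csf2ra without WT replicate 1, 0.071 for Fgd5 without WT replicate 2 and 0.092 for Mllt3 without Hif1a-/- replicate 1. In the interferon list, Parp14, Trim30a and Ddx58 differed by -0.29, -0.29 and -0.25, with groups that overlapped, and by -0.075, 0.010 and 0.12 without WT replicate 1. By limma, 1 stem cell gene, 1 granulocyte gene and 0 interferon genes had an unadjusted p under 0.05, and 0 in each list passed when adjusted over all genes or over the list alone.

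CDK inhibitors, p53 targets and apoptosis regulators differed little. The differences were -0.24 for Cdkn1b, -0.10 for Cdkn1c, 0.11 for Cdkn2a, 0.07 for Cdkn2b, -0.10 for Cdkn2c and -0.14 for Cdkn2d, with standard errors from 0.13 for Cdkn1c to 0.22 for Cdkn2d. Cdkn1a was not analysed here, since its probe set names several genes. A second probe set for Cdkn1b differed by -0.61. Without WT replicate 1 the differences were -0.12 for Cdkn1b, -0.028 for Cdkn1c, 0.038 for Cdkn2c and 0.19 for Cdkn2d, and without WT replicate 2 they were -0.022 for Cdkn2a and -0.18 for Cdkn2b. Camera gave adjusted p of 0.133 for 6 CDK inhibitors (mean -0.06), 0.476 for 25 p53 targets (mean -0.0063) and 0.0600 for 27 apoptosis regulators (mean -0.04). The CDK inhibitors had a mean of -0.24 without WT replicate 2 (adjusted p 0.00532), and of 0.11 without WT replicate 1. Perp, a p53 target at cell junctions, differed by -0.41, Btg2 by -0.33 and Zmat3 by 0.26. The executioner caspase gene Casp6 differed by -0.35, and the inhibitors of cell death Birc3 and Cflar by -0.20 each, with -0.31 for another probe set of Cflar. Without WT replicate 1 the differences were -0.13 for Perp, -0.023 for Btg2, -0.13 for Casp6, -0.0029 for Zmat3, -0.090 for Birc3 and -0.080 for Cflar. In these 3 lists, 0 genes had an unadjusted limma p under 0.05, and 0 passed when adjusted over all genes or over each list alone. For the p53 targets, camera gave the lower direction and fry the higher one.

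Lymphoid, stromal and antioxidant lists were not called. Dntt, the terminal transferase of early lymphoid cells, was 1.79-fold lower in Hif1a-/- cells, the interleukin-7 receptor gene Il7r differed by -0.62 (-0.088 without WT replicate 1) and Bcl11b by 0.23. Dntt differed by -0.84, and by -0.48 without Hif1a-/- replicate 2. The 26 lymphoid genes had a mean of -0.10, a median of 0.01 and the lower direction by camera (adjusted p 0.136). Their mean was 0.12 without WT replicate 1 (adjusted p 0.0260), -0.33 without WT replicate 2 (adjusted p 2.92e-06) and -0.18 without Hif1a-/- replicate 1 (adjusted p 0.00114). Pecam1, an adhesion molecule of endothelium and blood cells, differed by -0.40, while Col1a2 and Ibsp, genes of matrix and bone, each differed by 0.23, and by 0.14 and 0.13 without WT replicate 2. The 21 stromal and endothelial genes had a mean of -0.01, a median of 0.01 and the lower direction by camera (adjusted p 0.476). Among 20 antioxidant genes, Prdx2 and Gclc differed by 0.24 and 0.36 and Hmox1 by -0.38 (-0.030 without WT replicate 1), Gclc giving 0.10 without Hif1a-/- replicate 1, and the list mean was 0.05 (adjusted p 0.696). By limma, 1 lymphoid gene, 1 stromal gene and 0 antioxidant genes had an unadjusted p under 0.05, and 0 in each list passed when adjusted over all genes or over the list alone.

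**Figure D3:**
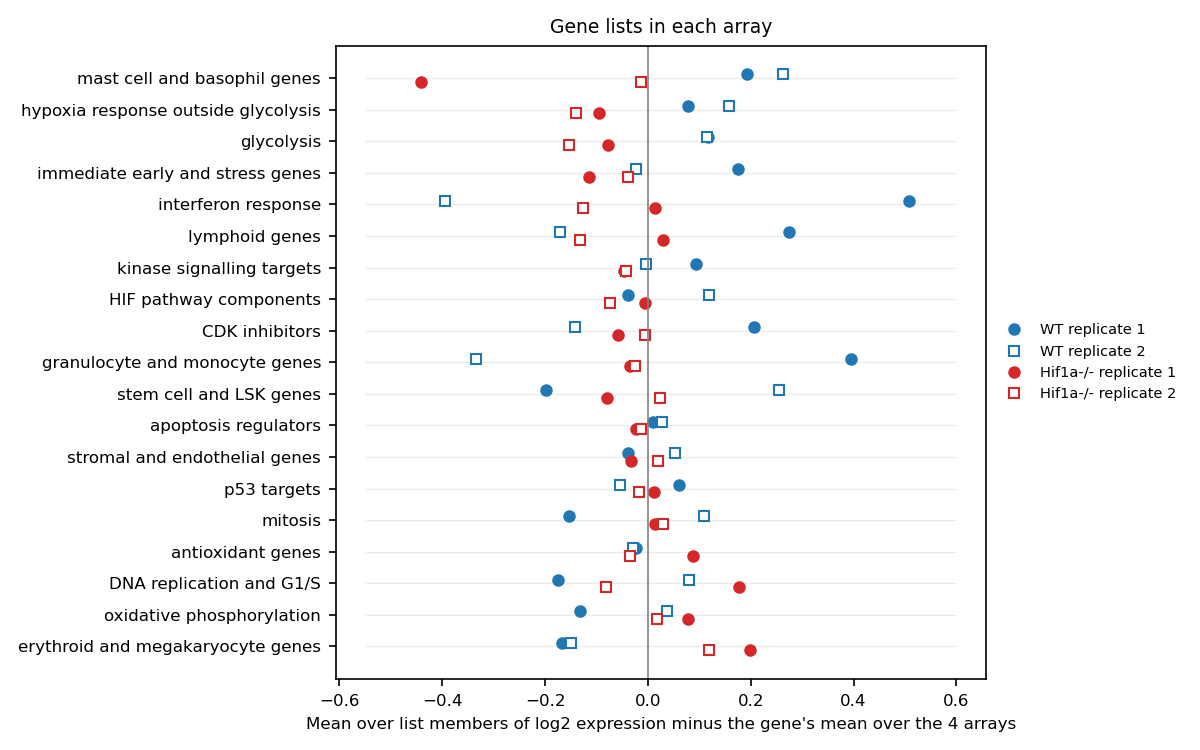
For each of the 19 lists, the mean over its genes of log2 expression minus the gene's mean over the 4 arrays, 1 point per array, WT in blue and Hif1a-/- in red. The mast cell, hypoxia, glycolysis and erythroid lists separate the genotypes by 0.17 or more, and the kinase, immediate early and apoptosis lists by 0.04 or less, while the interferon list spans from -0.39 to 0.51 on the WT arrays with the Hif1a-/- arrays between them.

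Over all genes, the differences at least 2-fold in size were few. The named genes with a mean at least 2-fold higher in Hif1a-/- cells were Sva, Pla2g4c and Xist, and 10 were lower: Mcpt4, Bnip3, Ifi205, Tnfrsf9, Mcpt1, Mcpt2, Gzmb, Uty, Tph1 and Eif2s3y. Tnfrsf9, the costimulatory receptor 4-1BB, read 10.91 ± 0.62 (SD, n = 2) in WT and 9.31 ± 0.57 (SD, n = 2) in Hif1a-/- cells, a 3.03-fold difference. The interferon-inducible gene Ifi205 was 2.08-fold lower (unadjusted limma p 7.65e-05), and Gzmb, granzyme B, 2.01-fold lower with groups that overlapped and a log2 difference of -1.01 that was -0.39 without Hif1a-/- replicate 1 and -0.47 without WT replicate 2. Pla2g4c, a cytosolic phospholipase, was 2.23-fold higher, with a log2 difference of 1.15 that was 0.72 without Hif1a-/- replicate 1. Sva differed by 1.56 at a mean below the 25th percentile of all genes, where the array separates signal from background poorly. Tph1, an enzyme of serotonin synthesis, read 8.90 on Hif1a-/- replicate 1 and 11.17 on Hif1a-/- replicate 2, and differed by -0.047 without Hif1a-/- replicate 1.

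By limma with Benjamini-Hochberg adjustment, 0 of 19938 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.239. At an unadjusted p under 0.05 there were 334 genes, 139 higher and 195 lower, where 997 are expected by chance. A variance trend called 1 gene (Sva), the trend with robust fitting 2 genes (Sva and Mcpt4), and leaving out a single array gave 349 genes without WT replicate 1, 1442 without WT replicate 2, 2 without Hif1a-/- replicate 1 (Xist and Eif2s3y) and 2 without Hif1a-/- replicate 2 (Mcpt2 and Mcpt1). In these fits the lone array is assumed to vary like the other genotype. Camera called 12 lists, 9 lower and 3 higher. In simulated data without any effect it called a median of 6 of 19 lists when arrays varied along the difference between the WT arrays. Some of the 12 calls can therefore be false. Fits with an array left out use the same preset correlation and share this limit. Of the 12 called lists, 0 kept the call with an estimated correlation, an option whose power was not measured. The estimates were -0.026 for glycolysis, -0.017 for hypoxia response and -0.013 for erythroid genes. These lie below the preset 0.01, so correlation between genes did not end those calls. The estimate was also below it for kinase signalling targets (0.0023). For the other called lists it lay above, from 0.086 for granulocyte genes to 0.85 for interferon genes, with 0.27 for mast cell genes. There the preset may understate the correlation, which would make the preset p too small. Of the 12 lists, 4 kept call and direction when each array was left out in turn: glycolysis, hypoxia response, erythroid and mast cell genes.

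The Hif1a-/- arrays differed in sex-linked genes. Xist, the RNA of the inactive X chromosome in female cells, read 11.56 on Hif1a-/- replicate 2 and 6.68 on Hif1a-/- replicate 1, against 7.12 and 7.76 on the WT arrays. The Y-linked genes went the other way: Eif2s3y read 7.89 on Hif1a-/- replicate 2 and between 9.99 and 10.18 on the other arrays, Kdm5d 7.26 against 8.45 to 9.09, and Uty 6.95 against 8.62 to 9.26. The genotype differences of Xist (1.68), Eif2s3y (-1.03), Kdm5d (-0.86) and Uty (-1.01) therefore rest on Hif1a-/- replicate 2. Without that array the differences were -0.77 for Xist, 0.11 for Eif2s3y, -0.21 for Kdm5d and -0.017 for Uty.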

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

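The array weights were added after the data had been seen; the other settings were fixed before the data were examined. The number of genes called (0 by limma, 334 at an unadjusted p under 0.05) was 1 with a variance trend, 2 with trend and robust fitting, and from 2 to 1442 with an array left out, and 0 with both filters, both scalings, the floor, both probe choices, array weights, an adjusted p under 0.1 and a 2-fold minimum. At an unadjusted p under 0.05 the split of 139 higher and 195 lower genes moved to 95 and 255 with centred medians, 267 and 187 with the trend and 275 and 187 with trend and robust fitting. The replicate numbers pair nothing that the labels name. The deviations of WT and Hif1a-/- replicate 1 correlated at -0.0072 across genes. That shows no pairing over all genes but does not exclude a shift shared by part of them. Gzmb read higher on replicate 2 in both genotypes (11.51 and 12.58 in WT, 10.42 and 11.65 in Hif1a-/- cells). Mmp8 read lower on replicate 2 in WT (12.09 and 9.53) and higher in Hif1a-/- cells (10.26 and 10.72). With the replicate number as a block, 47 genes and 13 lists were called. The number of lists called (12 of 19) was 0 with an estimated correlation, 1 with fry, 7 with the floor, from 8 to 13 with each other setting that kept all arrays, and from 9 to 14 with an array left out; the cause was not tested. Glycolysis and hypoxia genes kept call and direction in 16 of 18 settings, mast cell genes in 16 and erythroid genes in 17, the exceptions being the estimated correlation and, save for erythroid genes, fry. Hif1a stayed at an unadjusted p above 0.05 in every setting run.

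Outside the left-out arrays, 2 list directions turned, both of lists not called: p53 targets (-0.0063) with fry, and stromal genes (0.0040) without genes below the median. With an array left out, these list means turned direction at 1 or more arrays: interferon (-0.57 to 0.34), granulocyte (-0.42 to 0.30), lymphoid (-0.33 to 0.12), stem cell (-0.28 to 0.17), CDK inhibitors (-0.24 to 0.11), mitosis (-0.088 to 0.17), p53 targets (-0.063 to 0.051), DNA replication (-0.034 to 0.23), antioxidant (-0.0098 to 0.11), stromal (-0.060 to 0.032, by its mean alone) and oxidative phosphorylation (0.011 to 0.18, by its test alone). The genes of the naming rule that turned were Xist (-0.77 to 4.12), Eif2s3y (-2.18 to 0.11), Ddx58 (-0.62 to 0.12), Trim30a (-0.59 to 0.010), Cdkn2d (-0.47 to 0.19), Cdkn2c (-0.24 to 0.039), Cdkn2b (-0.18 to 0.32), Cdkn2a (-0.022 to 0.25), Rfc4 (-0.012 to 0.43) and Zmat3 (-0.0029 to 0.52). Of 139 genes examined singly, those of the naming rule and others picked after their values were seen, 108 shrank by over 1.5 times or turned without some array. Some of them were picked because the WT arrays differed in them, and the share over all genes was not computed, so this count does not describe genes at large. The genes and lists above turned without WT replicate 1, except the stem cell list, Cdkn2a and Cdkn2b without WT replicate 2, antioxidant genes without Hif1a-/- replicate 1, the stromal mean without WT replicate 2 or Hif1a-/- replicate 1, Xist and Eif2s3y without Hif1a-/- replicate 2, and DNA replication and Cdkn2c, which turned without either replicate 1. The p53 mean, though not its test, also turned without Hif1a-/- replicate 2 (0.0084). Sva lay at the floor on all arrays when a floor was set, which leaves no difference. Another background correction and a block for scan date were not run, since no scanner files were used here.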

Other observations

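The comparisons in this part and its 5 additional lists were chosen after the values had been seen. The main fit, the 20 earlier lists, the second quantile normalization and the left-out arrays that they draw on were fixed before. Genes of conventional dendritic cells and of antigen presentation read lower in Hif1a-/- cells. Xcr1 and Clec9a, receptors of cross-presenting dendritic cells, differed by -0.82 and -0.75, Itgae by -0.71 and Tlr3 by -0.67, and the MHC class II genes H2-Ab1, H2-Aa and H2-Eb1 by -0.74, -0.66 and -0.64, each with groups that did not overlap. Of 20 dendritic cell genes 16 had a lower mean (mean -0.33, camera adjusted p 1.77e-17). That gave adjusted p = 0.101 with an estimated correlation. All 9 measured MHC class II genes had a lower mean (mean -0.44, camera adjusted p 3.00e-16). Here too the adjusted p = 0.101 with an estimated correlation. By limma 0 of these genes passed when adjusted over all genes, while 7 dendritic cell and 5 MHC class II genes passed when adjusted over the list alone, which is no independent evidence because the lists were written after the differences were seen. The dendritic cell transcription factors Batf3 and Zbtb46 differed by 0.04 and 0.23 (-0.064 and 0.14 without WT replicate 2), and 9 plasmacytoid dendritic cell genes had a mean of 0.00046 and a median of -0.07 (camera lower, adjusted p 0.524), the mean lying between -0.052 without Hif1a-/- replicate 1 and 0.053 without Hif1a-/- replicate 2.

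The WT arrays differed from each other more than the Hif1a-/- arrays did. They stood 2-fold or more apart in 361 genes, against 33 for the Hif1a-/- arrays, with Pearson correlations across genes, which are not independent replicates, of 0.981 and 0.995. On WT replicate 1 the neutrophil genes Retnlg (13.03 against 10.50) and Mmp8 (12.09 against 9.53) and the interferon genes Ifit1 (11.61 against 9.48) and Mx1 (10.79 against 8.48) read higher than on WT replicate 2, and the progenitor genes Cd34 (10.31 against 12.30) and Cd27 (7.71 against 10.08) read lower. The Hif1a-/- arrays lay between them for all 6 of these genes. Between genotypes, 15 mature neutrophil genes had a mean difference of -0.06 (camera adjusted p 0.339), which was 0.88 without WT replicate 1 and -0.995 without WT replicate 2. The 5 early granule genes had a mean of 0.19 (camera adjusted p 0.0616), which turned to -0.069 without WT replicate 1 (adjusted p 0.378) and was 0.44 without WT replicate 2 (adjusted p 0.000198). Camera called the early granule list higher with the 25th percentile filter (adjusted p 0.0436), the median filter (0.0297), quantile normalization (0.0261), the variance trend with or without robust fitting (0.0421), the replicate number as a block (0.0275) and array weights (0.0321). With an estimated correlation, which was 0.97 for this list, camera gave it an adjusted p of 0.719, and fry gave an adjusted p of 0.958. The gene next to Hif1a in the gene order of GRCm38.p6, Snapc1, differed between genotypes by -0.62 (unadjusted limma p 0.0174; -0.35 without WT replicate 2), the 1 of 20 measured neighbours with an unadjusted p under 0.05.

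All 15 mature neutrophil genes read higher on WT replicate 1, by a mean of 3.66-fold, and 12 of them are also in the granulocyte list. Standard errors here and below are over the genes of a list, which can vary together, and hold no spread between samples. A sort with fewer of the gated cells stays open, since of the lists of other cell types lymphoid genes were higher there, by 0.45 (SE 0.11), while stromal genes were not (WT replicate 2 minus WT replicate 1, 0.09, SE 0.11), and erythroid genes, which the gated cells may transcribe themselves, decide nothing. A second quantile normalization left the neutrophil difference at 1.87 (SE 0.17), but RMA had already normalized the arrays by quantiles, so this decides nothing about the array scaling. Mature granulocytes that passed the lineage gate may account for it, with early granule genes, which mature granulocytes no longer transcribe, at -0.51 (SE 0.08), but replicate 2 minus replicate 1 was 0.26 (SE 0.03) for mitosis, 0.07 (SE 0.16) for mast cell and 0.02 (SE 0.08) for erythroid genes, which are not lower on replicate 1 by a like amount. The last 2 means average genes that went both ways, with 7 of 13 mast cell and 7 of 22 erythroid genes lower on replicate 1, so they decide little. Such granulocytes, a sort with fewer of the gated cells and a later granulocytic state of the gated cells cannot be told apart here. Each can raise mature neutrophil genes, and no biological explanation was tested.

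For the lower dendritic cell and MHC class II genes, a second quantile normalization left the MHC class II mean at -0.44 (SE 0.08). RMA had already normalized the arrays by quantiles, so this decides nothing about the scaling. B cells also make MHC class II, but the gate on lineage markers should remove them, and the 13 B-lineage genes of the lymphoid list decide little: their mean of -0.25 (SE 0.10) became 0.08 (SE 0.11) without WT replicate 1, where MHC class II stayed at -0.41 (SE 0.09). Fewer dendritic cells in the Hif1a-/- samples stay possible, with 16 of 20 genes lower, although the gate on c-Kit and Sca-1 should remove mature dendritic cells. The B-lineage mean also shrank to -0.08 (SE 0.07) without Hif1a-/- replicate 2, so it rests on that array and on WT replicate 1. For this reason, and because the dendritic cell list was written from the difference, fewer B cells or dendritic cells cannot be told apart from lower expression in the gated cells. An effect of the genotype on these genes remains open and was not tested apart from cell number.

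For the lower glycolysis and hypoxia genes, a second quantile normalization left the glycolysis mean at -0.22 (SE 0.06). The same limit holds, since RMA had already normalized the arrays by quantiles, so the scaling is not decided. Mature neutrophil genes lay 0.88 higher in Hif1a-/- cells than on WT replicate 2 and differed by -0.995 from WT replicate 1, yet the glycolysis mean was -0.23 against each of them (SE 0.06 and 0.09), which argues against granulocyte content. The hypoxia mean was -0.28 against WT replicate 2 and -0.20 against WT replicate 1. Lists of other cell types also differed by genotype (mast cell -0.46, dendritic cell -0.33, erythroid 0.32), and their share in the glycolysis and hypoxia means was not tested. The real grouping was the 1 of 3 splits of the arrays with a glycolysis mean as large, and the other splits gave -0.04 and 0.04, but 3 splits are too few for a share under 0.05. The split by genotype gave 12 called lists against 5 and 10, but 0 called genes against 2 and 0. It had the fewest genes at an unadjusted limma p under 0.05 (334 against 1082 and 1350). Both other splits set the WT arrays, which stood 2-fold or more apart in 361 genes, against each other. The genotype split keeps that difference within a group, where it widens the spread that its tests use. Sex-linked genes differ within the Hif1a-/- pair. Without Hif1a-/- replicate 2, the array that differs in them, the glycolysis mean was -0.19 and the hypoxia mean -0.21, so that array alone does not carry the difference. An effect of the genotype stays open as a hypothesis, since handling of the samples is not given in the labels and was not tested apart from genotype.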
